A study of Mus musculus with 9 samples.

How the data were processed

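RNA of cultured mouse cells was measured on 9 Affymetrix mouse expression arrays. Per the labels, the cells are preSC, preneoplastic neuroendocrine cells taken from the lungs of mice in which Adeno-Cre virus deleted conditional alleles of the genes for Rb, p53 and p130. The transduced groups are preSC carrying a retrovirus for L-Myc, C-Myc or N-Myc. Groups and replicate numbers were taken from the sample titles: 3 preSC arrays, 2 L-Myc arrays, 2 C-Myc arrays and 2 N-Myc arrays. The series' design text calls the replicates biological, and the labels name no shared culture, day or batch.

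The value table holds log2 values that the authors deposited, 1 per probe set and array. Per the submitters' processing notes, they were made with RMA in the affy package of R 3.0.1. RMA subtracts background, forces the arrays to a common distribution and fits 1 value per probe set, so a change of all transcripts in one direction would be lost, and large differences between dim probe sets are compressed. The version of affy is not given in the sources used here. The array medians lay between 6.02 and 6.07 on the log2 scale, so the table was used without further scaling. Scanner intensities were not used here. The number of arrays, not a read depth, limits the precision.

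The 45101 probe sets were named through a platform annotation table. Of these, 34958 gave 1 gene symbol, 932 gave several symbols and were given no gene, and 9211 were not listed in that table and are unnamed here. The 64 Affymetrix control probe sets are counted within these classes and were given no gene, which left 34945 probe sets with 1 gene. Of the probe sets with 1 symbol, controls included, 34754 matched a mouse RefSeq gene table (assembly GRCm38.p6) by Entrez identifier, and no symbol changed. The build behind the probe sets is not given in the sources used here, so no coordinates are printed, and the RefSeq table was used only for names and for which genes neighbour each other. Each of 18193 genes was represented by the probe set with the highest mean over all 9 arrays, and other probe sets of a gene were tested as an alternative. Where a probe set lies along its transcript was not analysed here.

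A gene was tested if its value was above the 40th percentile of all probe sets of an array in at least 2 of the 9 arrays, which left 12976 genes. The percentile lay between 5.28 and 5.34. Group means were fitted to all 9 arrays at once with limma 3.58.1 (lmFit and eBayes, R 4.3.3), since groups of 2 give little information on the spread. The fit leaves 5 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A gene said to have risen, fallen or changed passed this test. Fold changes are differences of group means of log2 values, with the standard error (SE) of the fit, and spreads within a group are standard deviations (SD).

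The 26 gene lists were fixed before the data were examined: MYC network, ribosome biogenesis, RNA polymerase I machinery, cytosolic ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, nucleotide and one-carbon synthesis, glycolysis, respiratory chain, mitotic and S-phase cell cycle, neuroendocrine markers, Notch pathway, mesenchymal state, epithelial adhesion, amino acid stress response, endoplasmic reticulum chaperones, cholesterol synthesis, hypoxia response, apoptosis regulators, interferon response and antigen presentation, immediate early genes, markers of fibroblasts and stroma, of endothelium, of leukocytes and of club, alveolar and ciliated cells, and sex-linked genes. The lists on ribosomes, RNA polymerase I and translation were written with knowledge of what had been published on L-Myc in small cell lung cancer, so they are not a blind choice. Of the 79 cytosolic ribosomal protein genes listed, 44 (55.7%) had a probe set with 1 gene symbol, which is too few to stand for the class; every other list had 80% or more. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Alternatives were camera with an estimated correlation and fry, a self-contained test.

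Genes named in the text were chosen by a rule fixed in the same way. The rule takes the genes for the 3 MYC proteins and the 3 deleted genes, and per comparison the 10 largest rises and the 10 largest falls among tested genes past the threshold whose arrays did not overlap, leaving out predicted genes. It adds, per list, up to 4 of the largest changes past the threshold, or up to 2 values where none passed, and a fixed set of genes that includes Chga, Syp, Ncam1, Calca, Hes1, Ncl, Fbl, Npm1, Polr1b, Xist and Ddx3y. The text gives a part of these. Trp53, Calca and Ddx3y were not analysed here, and 1 further gene of the fixed set is not reported here. Any other gene named was chosen after its values were seen, and the text says so.

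The planned comparisons were each transduced group against preSC, and C-Myc against N-Myc. The comparisons of L-Myc with C-Myc and with N-Myc were added after the control probe sets had been seen. Control probe sets were compared between the 3 preSC and the 6 transduced arrays with an exact permutation test of the difference of means (two-sided, 84 splits, 14 quantities, Benjamini-Hochberg). Alternatives tried were no filter, a filter at the 60th percentile, an intensity trend with robust eBayes, quantile normalization, arrays centred on their median, fits of only the groups compared, all probe sets or their mean, a 2-fold minimum, the replicate number as a block, and leaving out each array in turn. Centring on the median of the genes kept and the second-brightest probe set were added later. The latter holds only genes with at least 2 probe sets kept. It held 8 of 23 interferon, 7 of 21 immediate early, 9 of 23 epithelial adhesion and 10 of 20 glycolysis genes, so a call can also be lost through fewer genes. On data simulated for L-Myc against preSC over 12976 genes, the fit recovered 46% of 100 genes changed by 1 log2 unit and 84% of 100 changed by 2 log2 units, and 4.41% of its calls were false. The simulated noise was independent between genes and arrays and held no preparation difference, so these rates need not hold for the measured arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.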

Results

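Gene expression was measured in cultured mouse preSC, preneoplastic neuroendocrine lung cells lacking Rb, p53 and p130, and in the same cells transduced with a retrovirus for L-Myc, C-Myc or N-Myc. The 9 arrays comprised 3 preSC, 2 L-Myc, 2 C-Myc and 2 N-Myc arrays, and 12976 genes were tested. The deposited values are log2 RMA intensities, so the number of arrays limits the precision. Changes below are differences of group means on the log2 scale with the limma standard error (SE), from 3 preSC and 2 transduced arrays unless stated. Adjusted p-values for genes are from limma, and those for gene lists from camera. The p-values for genes measure the spread between these arrays, which the design text calls biological replicates. That spread was uneven: preSC 1 and 2 differed over 2-fold at 47 probe sets, and preSC 3 from them at 1909 and 1807. The N-Myc arrays differed at 13, the L-Myc arrays at 2252 and the C-Myc arrays at 3035. The labels do not say whether the closest arrays came from separate cultures, so their independence is not known. Those for lists compare the genes of a list with other genes at a preset correlation between genes. They do not measure how the level of a list varies between arrays. For ribosome biogenesis the estimated correlation was 0.53, above the preset value.

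The first question was whether each group carried the MYC gene its label names. Mycl, which encodes L-Myc, was measured with 3 probe sets. The second-brightest was 5.58 ± 0.17 (SD, n = 3) in preSC and 12.27 ± 0.67 (SD, n = 2) in L-Myc arrays, a rise of 6.69 (SE 0.51). The same probe set rose by 2.02 (SE 0.51) in C-Myc and by 1.53 (SE 0.51) in N-Myc arrays. The dimmest rose by 2.28 (SE 0.30), 1.91 (SE 0.30) and 1.72 (SE 0.30) in L-Myc, C-Myc and N-Myc arrays. The brightest Mycl probe set differed from preSC by -0.23 (SE 0.36) in L-Myc arrays and did not pass the test. Myc, which encodes C-Myc, was 7.15 ± 0.86 (SD, n = 3) in preSC, 6.46 ± 1.17 (SD, n = 2) in L-Myc, 10.95 ± 0.38 (SD, n = 2) in C-Myc and 11.68 ± 0.40 (SD, n = 2) in N-Myc arrays. Its rise was 3.80 (SE 0.60, adjusted p = 0.00376) in C-Myc arrays and 4.53 (SE 0.60, adjusted p = 0.00185) in N-Myc arrays, the adjustment running over the probe sets tested.

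The probe sets for Mycn, which encodes N-Myc, differed from each other. The dimmest of 3 rose in N-Myc arrays and did not pass in the other 2 groups. It went from 6.21 ± 0.17 (SD, n = 3) to 8.76 ± 0.42 (SD, n = 2), a change of 2.55 (SE 0.20, adjusted p = 0.000361). The brightest was 6.68 ± 0.28 (SD, n = 3) in preSC and rose by 6.44 (SE 0.26) in L-Myc, 6.63 (SE 0.26) in C-Myc and 4.67 (SE 0.26) in N-Myc arrays. Whether that probe set measured the Mycn transcript, vector sequence or a cross-hybridising one was not settled here, so its signal is not read as Mycn expression. The remaining one fell by 2.06 (SE 0.52) in C-Myc and by 2.71 (SE 0.52) in N-Myc arrays. Pvt1, a noncoding RNA gene beside Myc, was 5.98 ± 0.66 (SD, n = 3) in preSC, 13.58 in N-Myc 1, 13.63 in N-Myc 2, 13.11 in C-Myc 1 and 7.52 in C-Myc 2 on the brightest of 5 probe sets. The C-Myc arrays thus differed from each other in Pvt1 by 5.60, while their Myc values were 11.22 and 10.68. Rb1 and Rbl2, which encode the deleted Rb and p130, still gave signal, with Rb1 at 12.11 ± 0.26 (SD, n = 3) in preSC. Whether these probe sets lie in the deleted exons was not analysed here. Rb1 fell by 1.50 (SE 0.26) in C-Myc and by 1.50 (SE 0.26) in N-Myc arrays, and differed by -0.88 (SE 0.26) in L-Myc arrays, where it passed when adjusted over probe sets (adjusted p = 0.0438) but not over genes (adjusted p = 0.0620). The brighter Rbl2 probe set fell by 0.86 (SE 0.23) in N-Myc arrays and differed by -0.43 (SE 0.23) in C-Myc arrays and by less than 0.01 in L-Myc arrays. The other rose by 0.85 (SE 0.18, adjusted p = 0.0132 over probe sets) in L-Myc arrays and differed by 0.46 (SE 0.18) in C-Myc and by 0.24 (SE 0.18) in N-Myc arrays without passing, so Rbl2 is given no single direction.

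**Figure D1:**
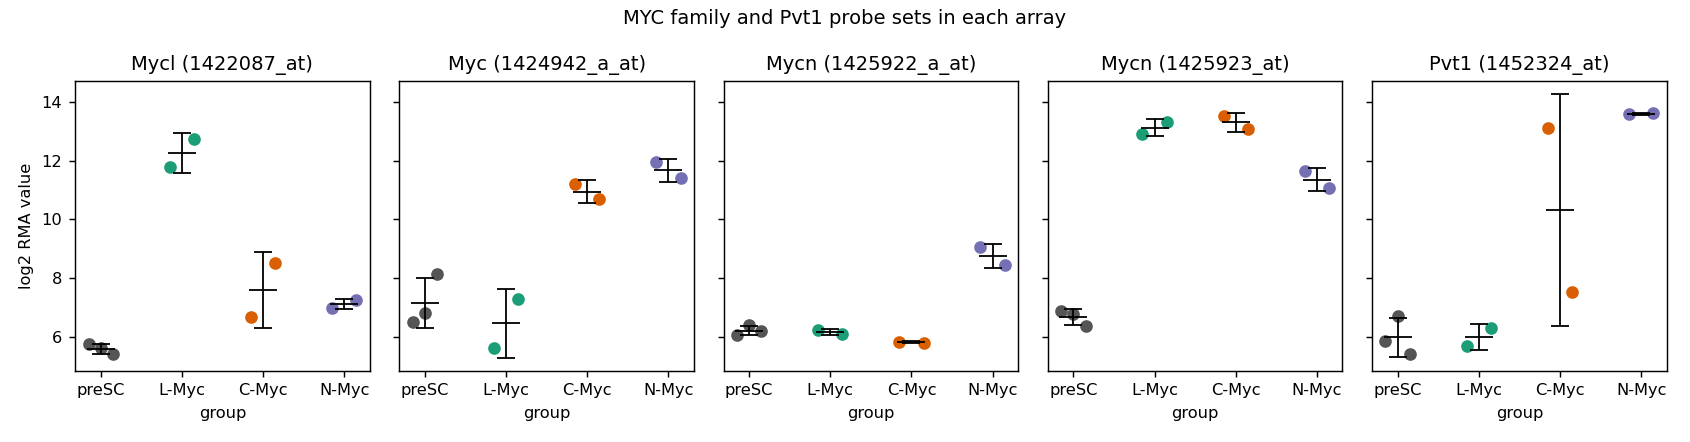
Log2 RMA value of 5 probe sets for Mycl, Myc, Mycn and Pvt1 (y axis) in each of the 9 arrays by group (x axis); points are arrays, and bars are the group mean ± SD. Mycl is highest in L-Myc arrays, Myc is high in C-Myc and N-Myc arrays, the brightest Mycn probe set is above 11 in the 6 transduced arrays, and Pvt1 is high in C-Myc 1 and both N-Myc arrays.

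The preSC arrays stood apart from the transduced arrays in several control probe sets, for ribosomal RNA, spiked-in transcripts and reference genes. The 18S ribosomal RNA signal was 13.25 ± 0.58 (SD, n = 3) in preSC and 8.85 ± 0.46 (SD, n = 6) in transduced arrays. For the spiked-in bacterial transcript Dap, the 5' minus 3' difference was -3.19 ± 0.16 (SD, n = 3) in preSC and -1.12 ± 0.11 (SD, n = 6) in transduced arrays. The same difference for Actb, the beta-actin gene, was -0.77 ± 0.13 (SD, n = 3) and -0.26 ± 0.04 (SD, n = 6). Each of these gave an exact permutation p of 0.0119 (two-sided, adjusted p = 0.0185 over 14 quantities), the smallest that the 84 splits allow. The BioB hybridisation control (exact permutation p = 0.452) and the Lys spike-in (exact permutation p = 0.381) did not pass. Per the labels, preSC and L-Myc samples were polyA RNA and C-Myc and N-Myc samples total RNA, so this separation does not follow the labelled molecule. Every comparison with preSC below coincides with it.

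**Figure D2:**
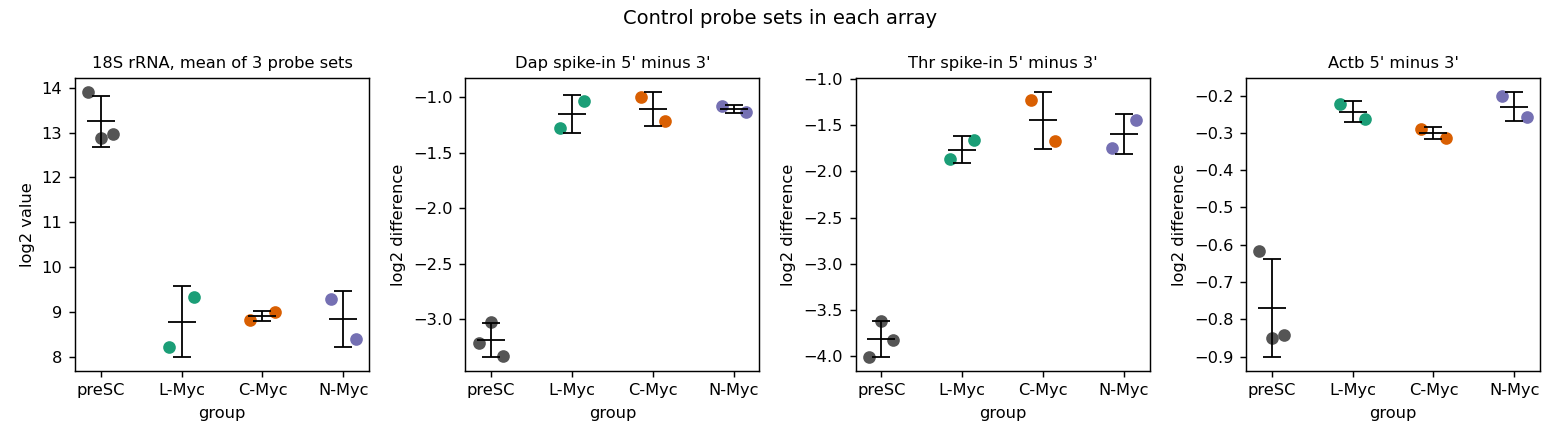
Control probe sets in each of the 9 arrays by group (x axis): the log2 value of 18S ribosomal RNA, and the log2 difference 5' minus 3' for the Dap and Thr spike-ins and Actb (y axes); points are arrays, and bars are the group mean ± SD. In all 4 panels the 3 preSC arrays lie apart from the 6 transduced arrays.

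In L-Myc against preSC, camera placed the lists for ribosome biogenesis, translation factors and nucleotide synthesis above other genes, with 16 of 91, 10 of 40 and 9 of 34 genes higher. It placed epithelial adhesion and antigen presentation below, with 5 of 23 and 3 of 23 genes lower, and adhesion was not called without L-Myc 1. None was called with an estimated correlation (adjusted p = 0.66 for translation factors and nucleotide synthesis and adjusted p = 0.77 for the others). Among the largest rises were Bcat1, a branched-chain amino acid transaminase, by 4.35 (SE 0.54), and the immediate early transcription factors Fosb, by 3.70 (SE 0.17), and Fos, by 3.22 (SE 0.19). Psme3, a proteasome activator subunit, rose by 3.03 (SE 0.27), Psmb7, a proteasome core subunit, by 2.68 (SE 0.22), and Nkx2-1, a lung lineage transcription factor, by 2.51 (SE 0.21). The largest falls included Smoc2, a matrix protein gene (-3.67, SE 0.43), the protocadherin gene Pcdh8 (-3.58, SE 0.53), Eppk1, which encodes the cytoskeletal linker epiplakin (-3.48, SE 0.49), Inhbb, an activin subunit (-3.44, SE 0.35), and Crabp1, which binds retinoic acid (-3.16, SE 0.58).

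The L-Myc comparison called 1748 of 12976 genes, 706 higher (40.4%) and 1042 lower, and 775 of them changed at least 2-fold (278 higher, 497 lower). The groups did not overlap for 6424 genes (49.5%), where chance gives 20%. Of 1007 called genes with a second-brightest probe set, 735 kept their direction on it. There 367 passed in the same direction and 78 in the opposite one. The split of directions rested on the scaling: the median change of all genes was -0.04, and centring arrays on the median of the genes tested moved it by 0.14 and called 1144 genes higher (62.0%) and 702 lower. The sign of the median also depended on the probe set. Over 6378 genes with a second-brightest probe set, it was -0.07 on brightest and 0.07 on second-brightest probe sets. Against preSC these medians were -0.09 and 0.08 in C-Myc and -0.09 and 0.09 in N-Myc arrays. List medians are therefore given relative to the median of all genes tested. Leaving out 1 array lowered the count to 712 without preSC 1, 603 without preSC 2, 1137 without preSC 3, 905 without L-Myc 1 and 638 without L-Myc 2. Of the 63 genes followed through these fits for this comparison, 58 passed, and 29 of those passed whichever array was left out. Many of the genes followed were picked because they passed in this fit, so these shares do not stand for all called genes. Camera called 10 of 26 lists, 7 of them higher, none with an estimated correlation, and fry called 5. The preSC arrays differed from the L-Myc arrays in 18S signal and spike-in values as well, though both groups were labelled polyA RNA.

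Of 91 ribosome biogenesis genes, 16 rose, 1 fell and 74 did not pass, with a list median of 0.48 (adjusted p = 3.28e-09). It had adjusted p = 0.77 with an estimated correlation, and 22 rose and 1 fell adjusted over the list alone. Fry did not call it (adjusted p = 0.122). This list and those for ribosomal proteins, translation and RNA polymerase I were chosen knowing published work on L-Myc. Nhp2 and Dkc1, subunits of the particles that guide pseudouridylation of ribosomal RNA, rose by 1.53 (SE 0.27) and 1.18 (SE 0.21). Ncl, which encodes nucleolin, rose by 0.78 (SE 0.20), and Fbl, the methyltransferase fibrillarin, by 0.73 (SE 0.18), though Ncl and Fbl did not pass without any 1 of the 5 arrays. Npm1, which encodes nucleophosmin, differed by 0.62 (SE 0.39) and did not pass. Of 15 RNA polymerase I genes, 2 rose, both also when adjusted over the list alone, and 13 did not pass: Taf1b, a subunit of the promoter selectivity factor, by 1.04 (SE 0.14), and the initiation factor Rrn3 by 0.79 (SE 0.17). Polr1b, the second largest subunit, differed by 0.21 (SE 0.36), and the list was not called (adjusted p = 0.237).

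Of 43 cytosolic ribosomal protein genes, which cover only part of that class, 15 rose, none fell and 28 did not pass (median 0.42, adjusted p = 1.42e-11), including Rpl12 by 1.34 (SE 0.30) and Rps25 by 1.26 (SE 0.14). Of 40 translation factor genes, 10 rose, none fell and 30 did not pass (median 0.48, adjusted p = 1.78e-08), including Eef1e1, an auxiliary protein of the tRNA synthetase complex, by 1.12 (SE 0.15), and the helicase Eif4a1 by 0.95 (SE 0.16). Of 21 aminoacyl-tRNA synthetase genes, 7 rose and 14 did not pass (median 0.59, adjusted p = 5.93e-05), including Sars, the seryl-tRNA synthetase, by 0.92 (SE 0.18), and the scaffold Aimp2 by 1.10 (SE 0.19). Of 34 nucleotide and one-carbon genes, 9 rose and 25 did not pass (median 0.45, adjusted p = 1.48e-05). Atic, an enzyme of the last steps of purine synthesis, rose by 1.49 (SE 0.22), the serine synthesis enzyme Phgdh by 1.10 (SE 0.25), and Shmt1, a one-carbon enzyme, by 1.47 (SE 0.38), while another Shmt1 probe set differed by -0.03. All 4 of these lists had adjusted p = 0.66 with an estimated correlation. Adjusted over the list alone, 24, 13, 10 and 10 genes rose in them in this order, and 1 fell in the last. The synthetase list was not called on second-brightest probe sets (median 0.56, adjusted p = 0.0628), and fry called neither it (adjusted p = 0.0550) nor the nucleotide list (adjusted p = 0.0568).

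**Figure D3:**
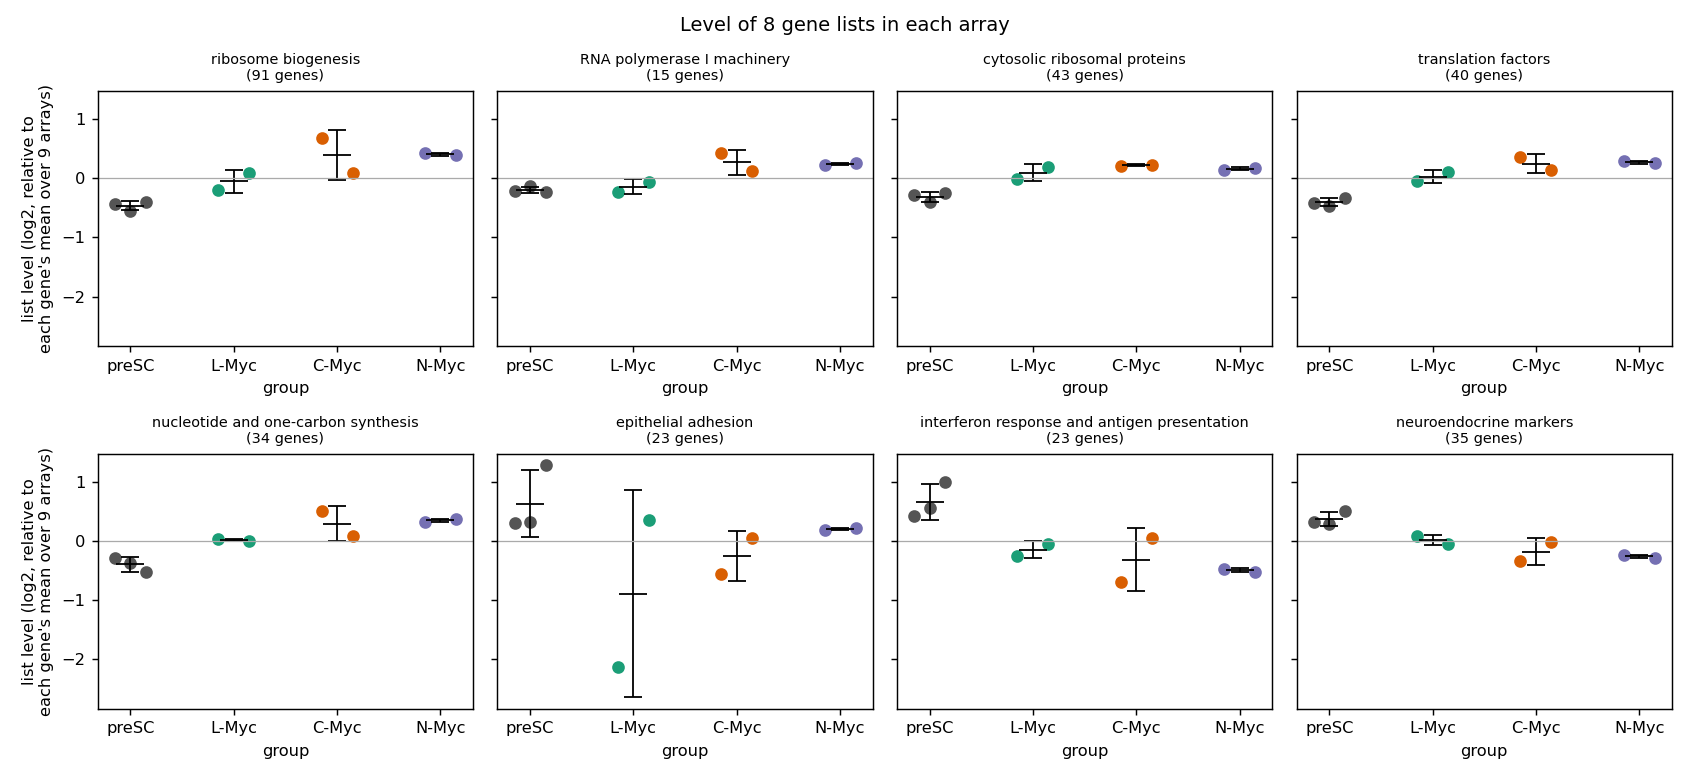
Median over list members of the log2 value minus the gene's mean over the 9 arrays (y axis) for 8 gene lists in each array by group (x axis); points are arrays, and bars are the group mean ± SD. Ribosome biogenesis lies at -0.47 ± 0.08 in preSC, -0.05 ± 0.20 in L-Myc, 0.39 ± 0.42 in C-Myc and 0.40 ± 0.02 in N-Myc arrays, and epithelial adhesion at -2.13 in L-Myc 1 and 0.35 in L-Myc 2.

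The neuroendocrine list was not called in L-Myc arrays (35 genes, median -0.25, adjusted p = 0.195), with 3 genes higher, 7 lower and 25 not passing, and 3 and 8 adjusted over the list alone. The secretory granule genes Scg2 (-1.93, SE 0.40) and Chga, chromogranin A (-0.84, SE 0.21), fell, and Syp, synaptophysin, rose by 0.99 (SE 0.18), as did the neuronal ubiquitin hydrolase gene Uchl1, by 1.16 (SE 0.18). Stx1a, a syntaxin, fell by 1.46 (SE 0.17), but differed by 0.15 on another probe set. Ncam1, an adhesion molecule, differed by -0.89 (SE 0.30) without passing and by 0.22 to 0.48 on 3 other probe sets. Of 23 epithelial adhesion genes, 5 fell and 18 did not pass (median -1.60, adjusted p = 5.93e-05, and adjusted p = 0.77 with an estimated correlation), as many as adjusted over the list alone. Cdh1, E-cadherin, fell by 2.47 (SE 0.50), the splicing factor Esrp1 by 2.25 (SE 0.58) and the plakophilin gene Pkp3 by 1.37 (SE 0.25). This fall lay mostly in L-Myc 1, and without that array the median was -0.47 (adjusted p = 0.0671), while without L-Myc 2 it was -2.93. Fry did not call it (adjusted p = 0.122).

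Of 23 interferon and antigen presentation genes, 3 fell and 20 did not pass (median -0.65, adjusted p = 0.00194, and adjusted p = 0.77 with an estimated correlation). Tap2, a peptide transporter, fell by 1.23 (SE 0.33), and Tapbp, tapasin, by 1.52 (SE 0.37), the latter differing by 0.18 on another probe set. The list was not called on second-brightest probe sets (median -0.20, adjusted p = 0.847) or by fry (adjusted p = 0.0846), and without preSC 3 its median was -0.37. Of 20 endoplasmic reticulum chaperone genes, 2 fell and 18 did not pass (median -0.20, adjusted p = 0.0496, and adjusted p = 0.77 with an estimated correlation). These were Hspa5, the chaperone BiP (-0.73, SE 0.18), and Dnajc3 (-0.93, SE 0.14), whose other probe set differed by 0.01. The chaperone list was not called without preSC 3 (median -0.07, adjusted p = 0.248) or without L-Myc 1 (median -0.09, adjusted p = 0.384), with arrays centred on the genes tested (adjusted p = 0.0767), with the mean of probe sets (median -0.07, adjusted p = 0.654) or by fry (adjusted p = 0.122), and it turned to 0.11 on second-brightest probe sets. Of 21 immediate early genes, 5 rose, 1 fell and 15 did not pass (median 0.32, adjusted p = 0.0192, and adjusted p = 0.66 with an estimated correlation), with Egr1, a zinc finger factor, up by 1.86 (SE 0.46). Without L-Myc 2 that list had a median of 0.26 (adjusted p = 0.0972), with the mean of probe sets 0.20 (adjusted p = 0.105), and on second-brightest probe sets -0.11 (adjusted p = 0.609). Of 56 respiratory chain genes, 5 rose, 2 fell and 49 did not pass (median 0.18, adjusted p = 0.00777, and adjusted p = 0.77 with an estimated correlation), including Sdhc, a subunit of complex II, by 1.57 (SE 0.19). Its median was 0.12 (adjusted p = 0.0679) without preSC 3, 0.11 (adjusted p = 0.180) with quantile normalization, 0.10 (adjusted p = 0.118) with the mean of probe sets and 0.063 (adjusted p = 0.782) on second-brightest probe sets, so this call was weak. The respiratory chain was not called by fry either (adjusted p = 0.122). Adjusted over the list alone, 3 interferon genes and 2 chaperones fell, 8 immediate early genes rose and 3 fell, and 5 respiratory chain genes rose and 2 fell. Second-brightest probe sets covered 8 interferon, 13 chaperone, 7 immediate early and 38 respiratory chain genes. On their brightest probe sets the same genes had medians of -0.57, -0.20, 0.11 and 0.23.

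In C-Myc against preSC, camera placed ribosome biogenesis and translation factors above other genes, with 54 of 91 and 28 of 40 genes higher, and neuroendocrine and antigen presentation genes below, with 13 of 35 and 6 of 23 lower. None was called with an estimated correlation (adjusted p = 0.57 for antigen presentation and adjusted p = 0.51 for the others), and the neuroendocrine median turned positive on second-brightest probe sets. Serpinb12, a serine protease inhibitor gene, rose by 5.71 (SE 1.64), Bcat1 by 4.85 (SE 0.54), Fosb by 3.91 (SE 0.17), Igfbp2, which binds insulin-like growth factors, by 3.83 (SE 1.10), Psme3 by 3.78 (SE 0.27) and Fos by 3.48 (SE 0.19). The largest falls included Chl1, a neural adhesion molecule (-5.32, SE 1.16), AI467606 (-5.24, SE 0.35), Pcdh8 (-4.59, SE 0.53), Egfl6, an EGF repeat protein (-4.21, SE 1.15), and the nuclear noncoding RNA Neat1 (-3.64, SE 0.92), which differed by 0.25 on another probe set. In preSC, Serpinb12 was 8.54 in preSC 3 and at most 5.05 in the other 2 arrays.

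Limma called 3049 genes here, 1286 higher (42.2%) and 1763 lower, of which 1386 changed at least 2-fold (495 higher, 891 lower). The groups did not overlap for 6795 genes (52.4%), where chance gives 20%. Of 1775 called genes with a second-brightest probe set, 1326 kept their direction on it. There 739 passed in the same direction and 130 in the opposite one. With arrays centred on the median of the genes tested, which moved the median change of all genes by 0.17, 2064 were called higher (63.4%) and 1192 lower. The count was 1585 without preSC 1, 1360 without preSC 2 and 1583 without C-Myc 1, and 1827 when only the 2 groups were fitted. Of 66 genes followed through these fits, 62 passed, and 43 of those passed whichever array was left out. These genes too were picked largely because they passed, so they do not stand for all called genes. Camera called 10 of 26 lists, 7 of them higher, none with an estimated correlation, and fry called 13. The 3 preSC arrays also differed in 18S signal, 13.25 against 8.85 in transduced arrays, and the labelled molecule of C-Myc samples was total RNA.

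Of 91 ribosome biogenesis genes, 54 rose, none fell and 37 did not pass, with a median of 0.95 (adjusted p = 9.60e-20), and 63 rose adjusted over the list alone. Without C-Myc 1 the median was 0.60. The list had adjusted p = 0.51 with an estimated correlation, being again chosen knowing published work. Nhp2 rose by 2.14 (SE 0.27), Dkc1 by 1.88 (SE 0.21), Fbl by 1.31 (SE 0.18) and Ncl by 1.18 (SE 0.20), while Npm1 differed by 0.92 (SE 0.39) and did not pass. Of 15 RNA polymerase I genes, 5 rose, none fell and 10 did not pass (median 0.45, adjusted p = 0.000523, and adjusted p = 0.51 with an estimated correlation), with 6 adjusted over the list alone. Polr1a, the catalytic subunit, rose by 1.31 (SE 0.27) and Taf1b by 1.08 (SE 0.14), and Polr1b differed by 0.94 (SE 0.36) without passing. The list median was 0.26 without C-Myc 1 and 0.72 without C-Myc 2. Of 43 ribosomal protein genes, 28 rose and 15 did not pass (median 0.60), with Rpl12 up by 2.24 (SE 0.30) and Rpl22 by 1.21 (SE 0.26). Of 40 translation factor genes, 28 rose and 12 did not pass (median 0.76), with the initiation factor Eif1a up by 2.00 (SE 0.30).

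Of 21 aminoacyl-tRNA synthetase genes, 11 rose and 10 did not pass (median 0.61), with Aimp2 up by 1.33 (SE 0.19) and the phenylalanyl-tRNA synthetase Farsa by 1.03 (SE 0.22), Farsa differing by -0.03 on another probe set. Of 34 nucleotide and one-carbon genes, 16 rose and 18 did not pass (median 0.68), with Shmt1 up by 2.58 (SE 0.38), Atic by 1.87 (SE 0.22) and Phgdh by 1.40 (SE 0.25). The camera adjusted p of these ribosomal protein, translation factor, synthetase and nucleotide lists was 5.21e-13, 2.07e-10, 1.13e-05 and 5.56e-07, and all 4 had adjusted p = 0.51 with an estimated correlation. Adjusted over the list alone, 33, 30, 12 and 16 genes rose in them, and 1 ribosomal protein and 1 translation factor gene fell.

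Of 35 neuroendocrine genes, 3 rose, 13 fell and 19 did not pass in C-Myc arrays (median -0.49, adjusted p = 0.00937, and adjusted p = 0.51 with an estimated correlation), with 3 and 18 adjusted over the list alone. Scg2 fell by 2.42 (SE 0.40), Chga by 1.32 (SE 0.21) and Ncam1 by 1.60 (SE 0.30), while Nkx2-1 rose by 2.53 (SE 0.21) and Syp by 1.18 (SE 0.18). The fall of this list was not seen on second-brightest probe sets, where 16 genes had a median of 0.05, and 1 other Ncam1 probe set differed by 0.25. Without C-Myc 1 the list had a median of -0.38 (adjusted p = 0.0595). Of 23 epithelial adhesion genes, 4 fell and 19 did not pass (median -0.97, adjusted p = 0.0493, and adjusted p = 0.85 with an estimated correlation), the same number adjusted over the list alone. Cdh1 fell by 1.84 (SE 0.50) and Tjp3, a tight junction protein, by 1.78 (SE 0.39). Fry did not call the adhesion list (adjusted p = 0.334). That list was not called without preSC 3 (median -0.50, adjusted p = 0.303) or without C-Myc 1 (median -0.51, adjusted p = 0.288), nor on second-brightest probe sets (median -0.66, adjusted p = 0.245).

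Of 23 interferon and antigen presentation genes, 6 fell and 17 did not pass (median -1.13, adjusted p = 0.00276, and adjusted p = 0.57 with an estimated correlation), and 10 fell adjusted over the list alone. The immunoproteasome subunit Psmb9 fell by 2.12 (SE 0.54), B2m, beta-2 microglobulin, by 2.01 (SE 0.58), and Ifih1, a sensor of double-stranded RNA, by 1.95 (SE 0.38). The list was not called on second-brightest probe sets (median -0.70, adjusted p = 0.693). Its size rested on C-Myc 1: the list level was -0.69 in C-Myc 1 and 0.06 in C-Myc 2, and the median was -0.29 without C-Myc 1, -0.71 without preSC 3 and -0.39 without the filter. Of 21 immediate early genes, 8 rose, 1 fell and 12 did not pass (median 0.51, adjusted p = 0.00801, and adjusted p = 0.51 with an estimated correlation), the same numbers adjusted over the list alone. Among them Egr1 rose by 2.06 (SE 0.46) and Ier2 by 1.77 (SE 0.47). The median of this list was 0.25 without C-Myc 1, and on second-brightest probe sets it was 0.13 (adjusted p = 0.895) and not called.

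In N-Myc against preSC, camera placed ribosome biogenesis, translation factors and glycolysis above other genes, with 58 of 91, 28 of 40 and 7 of 20 genes higher, and neuroendocrine and antigen presentation genes below, with 16 of 35 and 11 of 23 lower. None was called with an estimated correlation (adjusted p = 0.45 for each). On second-brightest probe sets glycolysis had a median of 0.38 (adjusted p = 0.554), and with the mean of probe sets the neuroendocrine median was -0.31 (adjusted p = 0.0666). Klhl41, a gene known from skeletal muscle, rose by 5.78 (SE 1.25), Serpinb12 by 5.29 (SE 1.64), Bcat1 by 5.11 (SE 0.54), Fosb by 4.76 (SE 0.17) and Fos by 4.20 (SE 0.19). The largest falls were Ctsz, a lysosomal cathepsin (-7.88, SE 1.95), Wfdc2, an epithelial secreted protein (-6.96, SE 1.69), and Phtf2 (-6.66, SE 1.55). Their N-Myc values lay between 3.06 and 4.70, below the 40th percentile of probe sets (5.34 and 5.32), so background limits the size and order of these falls. Chl1 fell by 5.61 (SE 1.16), AI467606 by 5.59 (SE 0.35), the scramblase gene Plscr4 by 5.47 (SE 1.03), Pcdh8 by 5.12 (SE 0.53) and the adhesion molecule gene Alcam by 4.94 (SE 1.40).

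Limma called 3741 genes here, 1617 higher (43.2%) and 2124 lower, of which 1756 changed at least 2-fold (625 higher, 1131 lower). The groups did not overlap for 8508 genes (65.6%), where chance gives 20%. Of 2117 called genes with a second-brightest probe set, 1620 kept their direction on it. There 950 passed in the same direction and 142 in the opposite one. Centring on the median of the genes tested moved the median of all genes by 0.17 and called 2662 higher (63.7%) and 1518 lower. The count was 2112 without preSC 1, 1831 without preSC 2, 564 without N-Myc 1 and 540 without N-Myc 2. Of 76 genes followed through these fits, 74 passed, and 29 of those passed whichever array was left out. Here as well the genes followed were picked largely because they passed and do not stand for all called genes. Camera called 11 of 26 lists, 8 of them higher, none with an estimated correlation, and fry called 14. The spike-in and 18S differences of the preSC arrays coincide with this comparison too, and N-Myc samples were labelled total RNA.

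Of 91 ribosome biogenesis genes, 58 rose, none fell and 33 did not pass (median 0.86, adjusted p = 8.63e-17, and adjusted p = 0.45 with an estimated correlation), with 63 adjusted over the list alone, a list chosen knowing published work. Nhp2 rose by 2.17 (SE 0.27), Dkc1 by 1.98 (SE 0.21), Fbl by 1.33 (SE 0.18), Ncl by 1.30 (SE 0.20) and Npm1 by 1.28 (SE 0.39). Of 15 RNA polymerase I genes, 6 rose and 9 did not pass (median 0.44, adjusted p = 0.00338, and adjusted p = 0.45 with an estimated correlation), with 7 adjusted over the list alone, but on second-brightest probe sets it had adjusted p = 0.0505. Polr1a rose by 1.49 (SE 0.27), Polr1b by 1.31 (SE 0.36) and Taf1b by 1.18 (SE 0.14). Of 43 ribosomal protein genes, 26 rose and 17 did not pass (median 0.51), with Rpl12 up by 2.14 (SE 0.30) and Rpl22 by 1.50 (SE 0.26). Of 40 translation factor genes, 28 rose, 2 fell and 10 did not pass (median 0.74), with Eif1a up by 1.60 (SE 0.30).

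Of 21 aminoacyl-tRNA synthetase genes, 10 rose and 11 did not pass (median 0.58), with Aimp2 up by 1.45 (SE 0.19) and Farsa by 1.24 (SE 0.22), though another Farsa probe set differed by -0.07. Of 34 nucleotide and one-carbon genes, 16 rose and 18 did not pass (median 0.82), with Shmt1 up by 2.91 (SE 0.38), Atic by 2.04 (SE 0.22) and Phgdh by 1.55 (SE 0.25). Of 20 glycolysis genes, 7 rose, 1 fell and 12 did not pass (median 0.65), as many as adjusted over the list alone. The phosphofructokinase gene Pfkl rose by 3.19 (SE 0.39), the lactate transporter Slc16a1 by 1.69 (SE 0.51), pyruvate kinase Pkm by 1.48 (SE 0.15) and lactate dehydrogenase Ldha by 1.24 (SE 0.23), while the glucose transporter Slc2a1 fell by 0.96 (SE 0.27) but differed by 0.01 on another probe set. The camera adjusted p of the ribosomal protein, translation factor, synthetase, nucleotide and glycolysis lists was 2.61e-09, 3.71e-09, 1.99e-05, 6.91e-07 and 0.00566, and all 5 had adjusted p = 0.45 with an estimated correlation. Adjusted over the list alone, 30, 30, 16 and 18 genes of the first 4 rose, and 2 translation factor genes and 1 nucleotide gene fell. The synthetase list was not called on second-brightest probe sets (median 0.76, adjusted p = 0.0505).

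Of 35 neuroendocrine genes, 3 rose, 16 fell and 16 did not pass in N-Myc arrays (median -0.58, adjusted p = 0.00566, and adjusted p = 0.45 with an estimated correlation), with 4 and 18 adjusted over the list alone. Dll3, a Notch ligand of neuroendocrine cells, fell by 2.47 (SE 0.45), the transcription factor gene Gfi1 by 2.04 (SE 0.48), Ncam1 by 1.94 (SE 0.30) and Chga by 1.36 (SE 0.21). Nkx2-1 rose by 2.65 (SE 0.21) and Syp by 1.23 (SE 0.18). On second-brightest probe sets the median of 16 of these genes was 0.08, and 1 other Ncam1 probe set differed by 0.29. Of 23 interferon and antigen presentation genes, 11 fell and 12 did not pass (median -0.98, adjusted p = 0.00103, and adjusted p = 0.45 with an estimated correlation), with 14 adjusted over the list alone. The immunoproteasome subunits Psmb8 and Psmb9 fell by 4.14 (SE 0.88) and 2.96 (SE 0.54), and the interferon-induced gene Ifit2 (-3.68, SE 0.92) and Ifih1 (-2.56, SE 0.38) fell as well. On second-brightest probe sets this list was not called (median -0.50, adjusted p = 0.559).

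Of 20 chaperone genes, 7 fell and 13 did not pass (median -0.34, adjusted p = 0.0121, and adjusted p = 0.72 with an estimated correlation), including Dnajc3 (-1.11, SE 0.14) and Xbp1, a regulator of the unfolded protein response (-1.10, SE 0.24). As many fell adjusted over the list alone, and without preSC 3 the list median was -0.24 (adjusted p = 0.0737). With the mean of probe sets it was -0.31 (adjusted p = 0.188), on second-brightest probe sets it turned to 0.12 (adjusted p = 0.886), and fry did not call it (adjusted p = 0.0573). Of 21 immediate early genes, 9 rose and 12 did not pass (median 0.70, adjusted p = 0.00134, and adjusted p = 0.45 with an estimated correlation), including Egr1 by 2.36 (SE 0.46) and Junb by 1.89 (SE 0.20). Adjusted over the list alone, 11 rose and 1 fell, but on second-brightest probe sets the list was not called (median 0.29, adjusted p = 0.886). Of 23 epithelial adhesion genes, 3 fell and 20 did not pass (median -0.41), and the list was not called (adjusted p = 0.231), with 1 gene lower adjusted over the list alone. Cdh1 fell by 1.60 (SE 0.50) and Pkp3 by 1.25 (SE 0.25).

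Camera did not call the following lists against preSC. For the L-Myc, C-Myc and N-Myc comparisons in this order, the camera adjusted p was 0.971, 0.825 and 0.855 for the 17 Notch pathway genes, of which 2 rose and 1 fell in each. Jag1, a Notch ligand, fell by 2.48 (SE 0.26), 2.17 (SE 0.26) and 1.93 (SE 0.26), and Lfng, which modifies Notch, rose by 1.49 (SE 0.21), 1.46 (SE 0.21) and 1.51 (SE 0.21). The Notch target Hes1 differed by -0.13 (SE 0.31), -0.20 (SE 0.31) and -0.01 (SE 0.31), none of which passed, with a sign that turned under other scalings in L-Myc and N-Myc arrays. Of 20 apoptosis regulators (adjusted p = 0.971, 0.855 and 0.855), 3 rose in each comparison and 1, 3 and 3 fell. The death agonist gene Bid rose by 2.17 (SE 0.15), 2.08 (SE 0.15) and 2.01 (SE 0.15). Mcl1, a survival gene, rose by 1.51 (SE 0.13), 1.45 (SE 0.13) and 1.59 (SE 0.13) on its brightest probe set and differed by -0.11 to -0.38 on 3 others. Bcl2l11, a death agonist, fell by 1.36 (SE 0.19) in L-Myc arrays, while another probe set rose by 1.13. Cflar, a caspase-8 inhibitor, fell by 2.19 (SE 0.41) in C-Myc arrays, where another probe set differed by 0.09, and by 2.51 (SE 0.41) in N-Myc arrays.

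Of 44 cell cycle genes (adjusted p = 0.179, 0.997 and 0.693), 5, 3 and 5 rose and 1, 3 and 8 fell. Cdc20, a mitotic regulator, fell by 0.72 (SE 0.15), 0.79 (SE 0.15) and 0.97 (SE 0.15), but differed by 0.05 and 0.07 on another probe set in L-Myc and C-Myc arrays. In N-Myc arrays E2f2 fell by 1.61 (SE 0.31) and Ccnb2, cyclin B2, by 1.47 (SE 0.42). Of 13 mesenchymal genes (adjusted p = 0.971, 0.996 and 0.693), 1 rose in each and 1, 2 and 1 fell: the integrin gene Itgb1 rose by 1.61 (SE 0.17), 1.63 (SE 0.17) and 1.43 (SE 0.17), and the hyaluronan receptor gene Cd44 fell by 1.57 (SE 0.26), 1.56 (SE 0.26) and 1.53 (SE 0.26). Of 19 cholesterol synthesis genes (adjusted p = 0.889, 0.355 and 0.0916), 0, 2 and 6 rose and 3, 2 and 1 fell. Pmvk, a kinase of the mevalonate pathway, fell by 0.92 (SE 0.17), 1.10 (SE 0.17) and 0.98 (SE 0.17), while Msmo1 and Fdps, later enzymes, rose in N-Myc arrays by 1.23 (SE 0.31) and 0.99 (SE 0.24). Of 16 hypoxia genes (adjusted p = 0.233, 0.499 and 0.730), 0, 1 and 1 rose and 1, 1 and 2 fell, and of 20 amino acid stress genes (adjusted p = 0.628, 0.355 and 0.688), 1, 4 and 4 rose and 1, 0 and 2 fell. Of 14 MYC network genes (adjusted p = 0.971, 0.855 and 0.855), 1, 2 and 2 rose and 0, 1 and 3 fell, but 1 of those that rose in each is the brightest Mycn probe set, which is not read as Mycn expression. Without Mycn, 0, 1 and 1 of 13 rose, the 1 being Myc. That list's median relative to all genes was negative in each comparison (-0.25, -0.10 and -0.13). Its mean, not taken relative to other genes, was positive (0.21, 0.45 and 0.27), and without Mycn it was negative (-0.27, -0.03 and -0.06). The median of all genes was -0.04, -0.05 and -0.03, so without Mycn the mean in C-Myc arrays lay above it.

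Glycolysis was not called in L-Myc (3 rose, 2 fell, adjusted p = 0.334) or C-Myc arrays (5 rose, 1 fell, adjusted p = 0.0547), where Pkm rose by 2.03 (SE 0.15) and 1.77 (SE 0.15). The respiratory chain was not called in C-Myc (7 rose, 3 fell, adjusted p = 0.0629) or N-Myc arrays (11 rose, 7 fell, adjusted p = 0.104), nor were the chaperones in C-Myc arrays (4 fell, adjusted p = 0.0615). Markers of other cell types were not called by camera in any of the 3. Fry called endothelial markers in L-Myc, C-Myc and N-Myc arrays (adjusted p = 0.0107, 0.00308 and 0.0203). It also called leukocyte markers in N-Myc arrays (adjusted p = 0.0347). Markers of club, alveolar and ciliated cells passed fry in C-Myc and N-Myc arrays (adjusted p = 0.0256 and 0.0374). In the order L-Myc, C-Myc and N-Myc, the camera adjusted p was 0.971, 0.935 and 0.688 for fibroblasts and stroma, with 0, 0 and 1 of 13 genes higher and 0, 1 and 0 lower. It was 0.526, 0.267 and 0.693 for endothelium, where 1 of 8 genes, the von Willebrand factor gene Vwf, fell by 3.06 (SE 0.33), 2.77 (SE 0.33) and 2.04 (SE 0.33). It was 0.628, 0.499 and 0.212 for leukocytes, with 0, 0 and 2 of 9 genes higher, and 0.586, 0.355 and 0.693 for club, alveolar and ciliated cells. Of those 8 genes 2 fell in each comparison, the alveolar lipid transporter gene Abca3 by 1.54 (SE 0.20), 1.80 (SE 0.20) and 2.03 (SE 0.20), and Ager by 0.92 (SE 0.18), 1.01 (SE 0.18) and 0.84 (SE 0.18). None of the 4 sex-linked genes passed, and Xist differed by at most 0.26 in size. The median relative to all genes, the mean, which is not relative to them, and the camera direction differed in sign for some lists. These were the fibroblast list in all 3 comparisons, Notch, mesenchymal and apoptosis genes in L-Myc arrays, and club, alveolar and ciliated markers in N-Myc arrays.

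The 3 comparisons with preSC shared 1289 genes that changed in the same direction, 551 higher and 738 lower. Independent lists of the same sizes would share 8.72 and 23.2, but the comparisons have the same 3 preSC arrays. Across genes, which are not independent replicates, the changes correlated with r = 0.85 for L-Myc and C-Myc, 0.65 for L-Myc and N-Myc and 0.89 for C-Myc and N-Myc. The covariances were 0.383, 0.336 and 0.549, where a simulation with shared controls and no changed genes gave 0.054, 0.049 and 0.052. In 50 further simulations of this kind, with independent noise per gene, 0 genes were shared by all 3. They held no changed genes and no preparation difference, so that count could hardly differ from 0. It does not bear on why the measured genes were shared. Bcat1, Fos, Fosb, Psme3, Nkx2-1, Nhp2, Dkc1, Bid and Sdhc rose, and Pcdh8, Jag1, Vwf, Cd44 and Abca3 fell, in all 3. The shared set was 569 without preSC 1, 469 without preSC 2, 795 without L-Myc 1, 451 without L-Myc 2, 394 without N-Myc 1 and 368 without N-Myc 2. It includes whatever sets the preSC preparation apart.

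Between C-Myc and N-Myc, both labelled total RNA, limma called 0 genes, with 541 at an unadjusted p below 0.05 and a smallest adjusted p of 0.936. The groups did not overlap for 33.1% of genes, where chance gives 33.3%. Camera and fry called 0 of 26 lists, the smallest camera adjusted p being 0.0647. The C-Myc arrays differed more from each other (r = 0.970 over probe sets) than C-Myc 1 did from N-Myc 1 (0.993) and N-Myc 2 (0.994), and the N-Myc arrays had r = 0.996. Without C-Myc 1, 421 genes were called, and camera called 6 lists without C-Myc 1, 11 without C-Myc 2 and 1 without N-Myc 2. Among genes singled out after their values were seen, Ctsz was 3.69 in C-Myc 1 and 11.90 in C-Myc 2, against 4.20 and 3.97 in the N-Myc arrays. Wfdc2 was 4.48 and 10.87, against 4.67 and 4.70, and Klhl41 was 10.33 and 5.08, against 9.86 and 9.97.

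L-Myc was compared with the other transduced groups after the control probe sets had been seen. The control probe sets were not tested between these groups. In the 5' and 3' probe sets of Dap and Thr both L-Myc arrays lay below the 4 other arrays, with Dap 5' at 10.15 and 10.37 against 10.47 to 10.71. Camera ranked the ribosome biogenesis list below other genes in L-Myc against C-Myc (median -0.43, adjusted p = 5.56e-22) and against N-Myc (median -0.47, adjusted p = 8.82e-09). None of its 91 genes passed alone in either comparison, also when adjusted over the list alone, and 3 and 13 of them had a positive difference. By array the list level was 0.087 in L-Myc 2 and 0.095 in C-Myc 2, so the difference from C-Myc was not seen between these 2 arrays. The list had adjusted p = 0.67 and adjusted p = 0.77 with an estimated correlation, and fry gave adjusted p-values of 0.429 and 0.307. RNA polymerase I genes had medians of -0.34 and -0.27, translation factors -0.18 and -0.12, nucleotide genes -0.22 and -0.32, and glycolysis genes -0.27 and -0.52. Neuroendocrine genes had medians of 0.25 and 0.34, cell cycle genes 0.12 and 0.27, and epithelial adhesion genes -0.64 and -1.04. Without L-Myc 1, the neuroendocrine medians were 0.13 (adjusted p = 0.116) and 0.20 (adjusted p = 0.298), and the cell cycle medians 0.026 (adjusted p = 0.240) and 0.16 (adjusted p = 0.204). Without C-Myc 1, those against C-Myc were 0.14 (adjusted p = 0.169) and 0.077 (adjusted p = 0.109). Without N-Myc 2 the neuroendocrine median against N-Myc had adjusted p = 0.0765, and on second-brightest probe sets the neuroendocrine medians were 0.10 (adjusted p = 0.439) and 0.098 (adjusted p = 0.986). Camera called all of these with a preset correlation, 9 lists against C-Myc, ribosomal proteins (-0.14) being the ninth, and 10 against N-Myc, cholesterol synthesis (-0.27) and immediate early genes (-0.35) included. With an estimated correlation or with fry it was 0 of 26 in both.

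With the preset correlation, only ribosome biogenesis was called in both comparisons without the filter, under every scaling and choice of probe sets tried and whichever array of the 2 groups was left out, with medians from -0.78 to -0.13 and from -0.59 to -0.29 without single arrays. Without L-Myc 1 the calls lost included ribosomal proteins against C-Myc (-0.061, adjusted p = 0.154) and, against N-Myc, RNA polymerase I (-0.20, adjusted p = 0.118), translation factors (-0.059, adjusted p = 0.483) and immediate early genes (-0.18, adjusted p = 0.154). Those lost without L-Myc 2 were nucleotide genes (-0.13, adjusted p = 0.0857, and -0.21, adjusted p = 0.0640) and glycolysis (-0.10, adjusted p = 0.259, and -0.55, adjusted p = 0.0640) in both comparisons, and cholesterol synthesis (-0.23, adjusted p = 0.147). Without C-Myc 1, translation factors were lost against C-Myc (-0.072, adjusted p = 0.0851) and RNA polymerase I was at -0.17, and without C-Myc 2 epithelial adhesion was lost there (-0.25, adjusted p = 0.489). Cholesterol synthesis was lost without N-Myc 2 too (-0.25, adjusted p = 0.0633). Ribosome biogenesis was the only list called against N-Myc on second-brightest probe sets, RNA polymerase I being at -0.11 (adjusted p = 0.572) and cholesterol synthesis at -0.32 (adjusted p = 0.352). With the mean of probe sets glycolysis was lost against C-Myc (-0.20, adjusted p = 0.0746), and translation factors (-0.13, adjusted p = 0.0655) and neuroendocrine genes (0.29, adjusted p = 0.0673) against N-Myc.

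No single gene was called by limma between L-Myc and C-Myc (0 genes, 602 at an unadjusted p below 0.05, smallest adjusted p = 0.830) or between L-Myc and N-Myc (0 genes, 2432 at an unadjusted p below 0.05, smallest adjusted p = 0.165). The groups did not overlap for 26.0% and 55.2% of genes, where chance gives 33.3%. Without C-Myc 2, 651 genes were called between L-Myc and C-Myc, and without L-Myc 2, 2 and 11 were called in the 2 comparisons. Fitting only the 2 groups called 241 between L-Myc and N-Myc. Ribosome biogenesis levels differed within groups as well, at 0.69 in C-Myc 1 and 0.09 in C-Myc 2, and at -0.20 in L-Myc 1 and 0.09 in L-Myc 2. Without L-Myc 1 the epithelial adhesion medians were 0.40 and 0.11 and camera called 4 lists against N-Myc, and without C-Myc 1 the nucleotide and glycolysis medians against C-Myc were 0.05 and 0.07. L-Myc samples were labelled polyA RNA and the others total RNA, so these differences coincide with the labelled molecule. L-Myc 2 and C-Myc 2 were the closest pair of arrays from different groups (r = 0.996).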

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

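Of the tests in this part, the one on second-brightest probe sets was set out before its result was seen, and the one on the gap between spike-in values was chosen afterwards. The spike-in control probe sets lie outside the comparisons of genes. The 5' probe set of the bacterial Dap transcript was 2.75 log2 units higher in the 6 transduced than in the 3 preSC arrays, and that of the Thr transcript was 2.90 higher. Both were above the level of every control array, and the exact permutation p was 0.0119 for each, the smallest the 84 splits allow. No group held 4 or more arrays, so no test for a single outlying array was run.

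The pattern weighed here is the higher level of ribosome biogenesis genes in transduced than in preSC arrays. A labelling difference that acts through the position of a probe set along its transcript could raise some probe sets of a gene and lower others. The list was still above all genes on second-brightest probe sets, where 54 genes had medians of 0.44, 0.77 and 0.75 in L-Myc, C-Myc and N-Myc arrays, with standard errors of the list mean across genes, which treat genes as independent, of 0.10, 0.12 and 0.12. The lowest of the 3, 0.44, was above 0 by more than 2 such errors, so the rise was not limited to brightest probe sets. On those, the same genes had medians of 0.543, 1.045 and 1.033. Where probe sets lie was not analysed, so a position effect common to both probe sets of a gene stays open. Array differences on the 2 brightest probe sets of a gene correlated at 0.42 to 0.65 between preSC and transduced arrays. For 11 pairs of transduced arrays with an SD of the difference of at least 0.52, this was 0.77 to 0.82. A preparation batch that coincides with preSC cannot be told apart from transduction for this list, since the 5' minus 3' value of Dap left a gap of 1.75 between the 2 sets of arrays and no preSC array lies with the transduced ones. An effect of the MYC proteins, which the design names, stays open for the same reason.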

How the results depend on the processing

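Fits with arrays centred on the median of genes, second-brightest probe sets, and the L-Myc against C-Myc and N-Myc comparisons were added after the data had been seen, and the other alternatives were planned. Leaving out an array moved 22 of 36 gene counts by over 1.5 times. Such fits hold fewer arrays and, in groups of 2, a lone array that is assumed to vary like the other groups, but some counts grew, as without C-Myc 1 or C-Myc 2. Fewer arrays and differences between the arrays of a group were not separated, and the cause was not tested. Named genes kept their direction and their side of the threshold in 729 of 1019 such values, and 282 kept only their direction. Filters, quantile normalization, centring and the intensity trend moved no total gene count by over 1.5 times, but centring on genes moved the genes called higher against preSC from 706 to 1144, 1286 to 2064 and 1617 to 2662. Among other probe sets of the named genes, 129 of 211 values kept direction and call, 47 kept only the direction, 1 passed where the brightest had not and 34 turned. RMA compresses differences between dim probe sets, so small changes near background are limited by signal. The replicate number was tried as a block, but the deviations of arrays with the same number correlated across genes at only -0.01 to 0.44, and the labels do not say that the numbers pair the samples. Of the preSC group, that check took only preSC 1 and 2. The difference of preSC 3 from their mean correlated at 0.745 with L-Myc 2 minus L-Myc 1. With C-Myc 2 minus C-Myc 1 it correlated at 0.431. Neither the check nor the block covers such a likeness, and no fit allowed for it. With the block, 1033 genes were called in L-Myc against preSC in place of 1748, and 46 of 50 list calls stood.

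A 2-fold minimum left 775, 1386 and 1756 genes in L-Myc, C-Myc and N-Myc against preSC and 486 of the genes shared by all 3, fewer by construction. Counting a gene once if any of its probe sets passed gave 3969, 5126 and 5871, and 1 gene between C-Myc and N-Myc, more by construction. Fitting only the groups compared gave 1827 for C-Myc against preSC and 241 for L-Myc against N-Myc, and the cause was not tested. On second-brightest probe sets camera called 5, 6 and 4 lists in the comparisons with preSC and 1 in L-Myc against N-Myc, with fewer genes per list. With the mean of probe sets it called 2 between C-Myc and N-Myc. With an estimated correlation camera called 0 lists in the 5 comparisons that had any, and the ribosome biogenesis medians of 0.48, 0.95, 0.86, -0.43 and -0.47 (L-Myc, C-Myc and N-Myc against preSC, then L-Myc against C-Myc and against N-Myc) had adjusted p-values of 0.771, 0.509, 0.453, 0.670 and 0.773. Fry called 5 lists in L-Myc against preSC and 0 in L-Myc against C-Myc and against N-Myc. It tests a list against no change, not against other genes, so it does not test the relative medians. For ribosome biogenesis fry gave adjusted p-values of 0.122, 0.429 and 0.307 in these comparisons.

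Leaving out 1 array at a time gave 603 to 1137 genes for L-Myc, 1360 to 3493 for C-Myc and 540 to 2850 for N-Myc against preSC. It gave 0 to 421 for C-Myc against N-Myc, 0 to 651 for L-Myc against C-Myc, 0 to 11 for L-Myc against N-Myc and 368 to 1594 for the shared genes. Camera called 8 to 10, 8 to 14 and 10 to 12 lists against preSC, and 0 to 11, 6 to 12 and 4 to 10 between the transduced groups in the order just given. The ribosome biogenesis median ranged from 0.32 to 0.60, 0.60 to 1.26 and 0.84 to 0.90 against preSC, from -0.78 to -0.13 in L-Myc against C-Myc, and from -0.59 to -0.29 in L-Myc against N-Myc. List medians that turned were epithelial adhesion without L-Myc 1, at 0.40 against C-Myc and 0.11 against N-Myc, and nucleotide genes at 0.046 and glycolysis genes at 0.075 in L-Myc against C-Myc without C-Myc 1. The range over such fits was -1.96 to 0.40 and -2.05 to 0.11 for adhesion, -0.47 to 0.046 for nucleotide genes and -0.56 to 0.075 for glycolysis.

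Hes1, which passed in no comparison, turned to 0.065 with quantile normalization and 0.029 with arrays centred on all probe sets in N-Myc arrays. Centring on genes gave 0.011 in L-Myc and 0.16 in N-Myc arrays, and the block gave 0.15, 0.078 and 0.27. Without single arrays it ranged from -0.38 to 0.15 in L-Myc, -0.44 to 0.078 in C-Myc and -0.25 to 0.27 in N-Myc arrays. On second-brightest probe sets, list medians turned to 0.11 (L-Myc) and 0.12 (N-Myc) for chaperones, -0.11 (L-Myc) for immediate early genes, and 0.047 (C-Myc) and 0.077 (N-Myc) for neuroendocrine genes.

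Other probe sets turned the following changes from preSC, and the cause was not tested. Mycn was -0.81 and -0.048 in L-Myc, -2.06 and -0.40 in C-Myc and -2.71 in N-Myc arrays. Mcl1 was -0.11, -0.15 and -0.14 in L-Myc, -0.38, -0.37 and -0.28 in C-Myc and -0.32, -0.30 and -0.30 in N-Myc arrays. Ncam1 was 0.48, 0.22 and 0.22 in L-Myc, 0.25 in C-Myc and 0.29 in N-Myc arrays. In L-Myc arrays Shmt1 was -0.031, Stx1a 0.15, Tapbp 0.18, Bcl2l11 1.13 and 0.071, Dnajc3 0.0078 and Cdc20 0.047. In C-Myc arrays Neat1 was 0.25, Farsa -0.032, Stx1a 0.36, Cflar 0.093 and Cdc20 0.069. In N-Myc arrays Farsa was -0.069, Rbl2 0.24 and Slc2a1 0.0081.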

Other observations

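All 4 tests of explanations in this part were chosen after the patterns had been seen. Genes on the Y chromosome were measured in all 9 arrays: Eif2s3y, a translation initiation factor gene, lay between 8.54 and 10.25, Kdm5d between 6.56 and 8.04, and Uty between 6.42 and 7.57, while Xist, the RNA that silences an X chromosome, lay between 4.92 and 5.38. A set of genes singled out after their values were seen separated arrays across the groups. Hdgfl3 was 6.96 in preSC 3, 6.73 in L-Myc 2 and 7.19 in C-Myc 2, and at least 9.76 in the other 6 arrays. Lyz2, which encodes lysozyme, was 5.61, 6.44 and 6.76 in the same 3 arrays and at least 9.31 in the others. Phtf2 was 3.62 in C-Myc 1, 3.06 in N-Myc 1 and 3.13 in N-Myc 2, and at least 9.42 elsewhere.

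L-Myc 2 and C-Myc 2 were closer to each other (r = 0.996, 41 probe sets apart by 2-fold or more) than to their own groups (L-Myc arrays r = 0.977, C-Myc arrays r = 0.970). A mislabelled or swapped array would need the MYC genes of these arrays to be alike or the wrong way round. On its second-brightest probe set, Mycl was 4.23 higher in L-Myc 2, and Myc differed by -3.40, against an SD of 0.20 over all probe sets. The dimmest Mycl probe set was nearly alike, at 7.24 in L-Myc 2 and 7.15 in C-Myc 2, as was the brightest, at 8.78 and 8.92. Myc and that 1 Mycl probe set argue against a swap between these arrays, and the other Mycl probe sets do not tell them apart. A difference already present among the preSC arrays is a candidate explanation: the difference of L-Myc 2 from L-Myc 1 correlated with that of preSC 3 from the mean of preSC 1 and 2 at r = 0.745 across genes, and that of C-Myc 2 from C-Myc 1 at r = 0.431. Genes are not independent replicates, and the labels do not say which cultures were transduced together.

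Myc and Pvt1 were both high in the N-Myc arrays and in C-Myc 1, while C-Myc 2 had Myc at 10.68 and Pvt1 at 7.52. Whether retroviral sequence adds to the Myc signal was not tested and stays open. A gain or activation of a wider region may apply. In N-Myc against preSC, which coincides with the difference in control probe sets, the mean change of the 4 measured genes that flank the pair was 1.15, at percentile 99.6 of 12844 windows of the same shape. Among these, Lratd2 changed by 2.35, Macroh2a3 by 1.65 and Gsdmcl2 by 0.43, and 4933412E24Rik differed by 0.17 without passing. Between C-Myc 1 and C-Myc 2, single arrays free of that difference, the mean was 0.88, at percentile 98.0, but it rested on 2 of the 4 genes: Lratd2 differed by 2.37 and Macroh2a3 by 1.16, against 0.06 for 4933412E24Rik and -0.06 for Gsdmcl2. Relative to preSC (10.38 to 10.87), part of the Lratd2 difference came from C-Myc 2, which at 9.27 lay below it, while C-Myc 1 was 11.64. The L-Myc arrays lay below preSC as well, at 8.62 and 9.22, so a low Lratd2 value was not particular to C-Myc 2. Macroh2a3 was 9.66 in C-Myc 1 and 8.49 in C-Myc 2, against 8.11 to 8.37 in preSC. A gain of copies, an insertion of the retrovirus nearby and an activation of the region by other means cannot be separated with these arrays.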
